A study of Mus musculus with 6 samples.

How the data were processed

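Bulk messenger RNA of whole lung was measured in 6 mice, 3 given phosphate-buffered saline (PBS) and 3 given diphtheria toxin (DT). Per the labels' protocols, all mice were chimeras carrying the toxin receptor under the control of Zbtb46, all breathed 10% oxygen for 7 days, and the toxin was given at 40 ng per g body weight 1 day before hypoxia and then at 8 ng per g every 3 days, 3 doses in all. Libraries were made with a kit that selects polyadenylated RNA, per the labels' protocols. FastQC, Trimmomatic and the mouse build mm10 are named in the submitters' processing notes, without versions. The aligner, the counting program and its use of strand are not given in the sources used here.

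The authors deposited log2 reads-per-million values (RPM) for 25965 genes, with gene symbol, Ensembl identifier and mm10 position. Back on the linear scale, the values above the lowest were whole multiples of what 1 read is worth, for 100% of them in every library at a tolerance of 0.1%, and the lowest value equalled 0.9 of a read and stood for genes with no read. This gave the total behind the per-million scale, which was 18027303, 18763687 and 19084657 reads in PBS mice 1 to 3 and 16766386, 18831937 and 18385833 in DT mice 1 to 3. Between 69.82% and 73.13% of that total lay in the listed genes. A gene with no read could hold up to 3 reads, or between 0.157 and 0.179 RPM, a limit that covers counting error only. A sheet named for read counts held gene labels and positions only, and another repeated the group means; neither was used here. Of the identifiers, 25035 were found in GENCODE M21, which gave current symbols and exonic lengths, and 24982 of these overlapped its mm10 position. Dates stood in place of 25 deposited symbols, which were restored through the identifier, and 65 identifiers were listed more than once. All 13 mitochondrially encoded genes were listed with no read in any library and were not tested.

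Groups were taken from the sample titles. A count model had been set as the main test before the data were examined, with limma on log2 values as the stated fallback for a deposited unit other than counts. Since the deposited unit is log2, the fallback was used: limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(RPM + 1), no further scaling, a 2-sided test of DT against PBS, Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate the change of low genes. Genes were tested where at least 3 libraries reached 0.538 RPM, which is 10 reads in the library of median depth, and where the total reached 15 reads, which left 16708 genes. Gene lists, 58 in all, were fixed before the data were examined, and 56 had the 3 tested members needed. They were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and p-values were adjusted over the 56 lists. Counts of list members past 0.05 are given over all genes tested and adjusted over the list alone.

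Genes named in the text followed a rule fixed before the data were examined: up to 12 of the largest rises and 12 of the largest falls among genes past the threshold with a mean of at least 1 RPM and no overlap between the groups, up to 4 members per list that passed or otherwise the most abundant 2, and a fixed set of dendritic, vascular, immune and sex-linked genes. Not every gene the rule covers is named. Genes named outside this rule are said to be chosen after their values were seen. Single measures per mouse were compared by a 2-sided exact permutation test, whose smallest p with 3 against 3 mice is 0.1.

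The model was tested on simulated data: counts were drawn for the 16708 genes from the real means, scatter and library sizes, with 200 genes changed. For the comparison of DT against PBS, limma recovered 58% of the 50 genes changed 1.5-fold, 76% at 2-fold, 90% at 4-fold and 98% at 8-fold, and 18 of its 179 calls (10.1%) were false, above the nominal 5%. Each gene was drawn independently and the changed genes were picked at random. Shifts that many genes share in 1 mouse were not simulated, so these shares may not hold for genes that vary together. Alternatives covered scaling (median of ratios, upper quartile, trimmed mean of M-values), the filter on low values, the pseudocount, limma-voom on the recovered reads, a replicate block, a minimum fold change of 1.2, camera on ranks, the variance prior and leaving out each mouse, with the numbers of the mice tested for pairing. Of these, the trimmed mean of M-values, the pseudocount, the deposited values without a pseudocount, the variance prior and the block with median-of-ratios scaling were added after the data were seen. Plots were drawn with matplotlib 3.10.9.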

Results

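Whole-lung RNA was profiled in 6 chimeric mice in which cells expressing Zbtb46, a transcription factor of classical dendritic cells (cDC), carried the diphtheria toxin receptor. All 6 mice were held in hypoxia (10% oxygen) for 7 days. Toxin (DT) was given to 3 of them to deplete cDC and vehicle (PBS) to the other 3. The comparison asked which lung processes change when cDC are removed in hypoxia that leads to pulmonary hypertension. No mice without the receptor were given toxin. An effect of cDC loss therefore cannot be told apart from an effect of toxin itself or on other cells with the receptor. Sequencing depth was 16766386 to 19084657 reads per library (mean 18630000 ± 542000 (SD, n = 3) in PBS and 17990000 ± 1090000 in DT, exact permutation p = 0.6). Levels are reads-per-million values (RPM) with the SD over 3 mice. Log2 fold changes of DT over PBS are given with their standard error.

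Several markers of classical dendritic cells were lower on average in toxin-treated lungs, but PBS mouse 1 was near the toxin group for several of them and none of those named here passed the test over all genes. Xcr1, the chemokine receptor of cDC1 cells (identifier ENSMUSG00000060509, mm10 chromosome 9, 123852315 to 123862029), averaged 14.1 ± 8.45 RPM in PBS and 3.46 ± 3.12 in DT, a log2 fold change of -1.88 ± 0.69 (-1.14 without DT mouse 3). Cd209a, a lectin of cDC2 cells, had a log2 fold change of -1.80 ± 0.56 and the necrotic cell receptor Clec9a one of -1.48 ± 0.41. The growth factor receptor Flt3 had a log2 fold change of -1.11 ± 0.48 and the integrin Itgae of -1.21 ± 0.54 (-0.75 for both without DT mouse 3). In PBS mouse 1, Xcr1 stood at 4.55 RPM against 17.3 and 20.5 in the other PBS mice, Cd209a at 1.78 against 11.6 and 13.1, and Flt3 at 3.22 against 11.1 and 13.2. Its Clec9a, at 5.05 RPM, lay just above the 3 DT mice (1.74 to 4.77), and its Zbtb46, at 108, was the highest of the 6. Zbtb46 itself, which lung endothelium also transcribes, was at 99 ± 9.52 RPM in PBS and 84.4 ± 2.62 in DT (log2 fold change -0.22 ± 0.07). Itgax differed by 0.11 ± 0.16 (-0.05 without PBS mouse 1 to 0.25 without PBS mouse 3), and Hbegf, the mouse counterpart of the toxin receptor gene, by 0.14 ± 0.05. Adjusted p-values for these genes ran from 0.337 for Clec9a to 0.89 for Itgax (limma, Benjamini-Hochberg).

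Of the 12 shared cDC markers, 0 rose or fell over all genes tested (limma) and 3 were lower when adjusted over the list alone. Their median log2 fold change was -0.50 and the list as a whole lay lower than other genes (camera, adjusted p = 0.00155; adjusted p = 0.735 with an estimated correlation). Of the 12 cDC1 markers, 0 passed over all genes and 0 when adjusted over the list alone, with a median of -0.06 and camera adjusted p = 0.0449, or adjusted p = 0.878 with an estimated correlation. This list held abundant members that lung epithelium also makes, such as Cadm1 (-0.06 ± 0.05) and Cd24a (0.03 ± 0.05). The cDC2 list, with 11 members tested, did not pass (camera adjusted p = 0.666); its median of 0.05 and its test pointed up while its mean of -0.13 pointed down. In that list Tnip3, an inhibitor of NF-kappaB signalling, rose from 5.62 ± 0.538 to 11.6 ± 0.29 RPM (adjusted p = 0.0154). The call for Tnip3 was lost without PBS mouse 2 (0.0608), DT mouse 1 (0.144) or DT mouse 3 (0.0987). When adjusted over the list alone, 1 member was higher and 2 were lower, and the chemokine Ccl17 had a log2 fold change of -0.59 ± 0.17. Class II antigen presentation genes did not pass as a list (13 tested, 0 past the test over all genes and 0 adjusted over the list alone, camera adjusted p = 0.273), with Cd74 at 0.01 ± 0.06 (0.00 under upper-quartile scaling) and H2-Ab1 at -0.05 ± 0.06. As a list they lay lower without PBS mouse 1 (0.0122) or DT mouse 1 (0.0196). Cd74 lay at 0.516 reads per exonic base, a density at which it was not tested whether values follow abundance. Mature migratory dendritic cell markers (12 tested, 0 past the test over all genes and 0 adjusted over the list alone, median -0.18, camera adjusted p = 0.0587; adjusted p = 0.838 with an estimated correlation) did not pass with all mice, and lay lower without PBS mouse 1 (0.00182) or DT mouse 1 (0.0217). Plasmacytoid dendritic cell markers pointed the other way: 7 of 10 were positive, with a median of 0.22, 0 past the test over all genes and 1 higher when adjusted over the list alone (camera adjusted p = 0.0587; adjusted p = 0.735 with an estimated correlation). That list lay higher without PBS mouse 2 (0.0139) or DT mouse 2 (0.0436). The cDC1 call was lost without PBS mouse 2 (adjusted p = 0.192), PBS mouse 3 (0.257), DT mouse 2 (0.163) or DT mouse 3 (0.152).

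**Figure D1:**
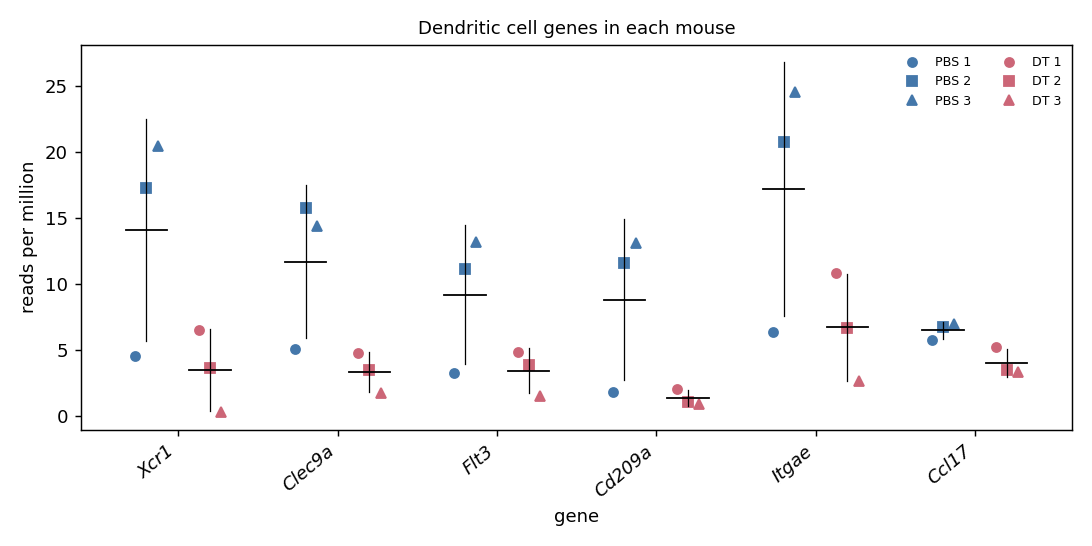
Level (RPM) of 6 dendritic cell genes in each mouse, with horizontal lines for group means and vertical lines for 1 SD (n = 3 mice per group). PBS mouse 1 lies near the toxin group for Xcr1 (4.55 RPM), Clec9a (5.05), Flt3 (3.22), Cd209a (1.78) and Itgae (6.32).

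Without PBS mouse 1, a mouse singled out after the data were seen, 10 genes were lower in DT in place of 1, and 56 were higher in place of 46. Cd209a was among those lower, at a log2 fold change of -2.55 (limma, adjusted p = 0.00867). The other 9, named after their values were seen, were Apol7c (-2.47), Cd207, which encodes langerin (-1.79), Hepacam2 (-1.72), Dnase1l3 (-1.37), Tlr12 (-0.96), Cldn1 (-0.67), Lrrn3 (-0.56), Snhg11 (-0.56) and Hr (-0.44). The shared cDC list then had a median of -0.79, with 1 of 12 members lower over all genes (camera adjusted p = 1.73e-09), and the cDC1 list an adjusted p of 0.000464. Since that mouse was singled out for its low dendritic cell markers, these values restate that observation and are no separate evidence of depletion. The shift was not particular to dendritic cells: in the same fit B cell markers had a median of -0.61 (1.73e-09), natural killer and cytotoxic cell markers of -0.47 (1.47e-09) and adipose markers of -0.95 (0.000381). These p-values rest on the preset correlation of 0.01, and with all 6 mice each of these lists lost its call with an estimated correlation, which was 0.34 for shared cDC, 0.39 for cDC1, 0.73 for natural killer, 0.83 for adipose and 0.86 for B cell markers.

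Several genes of the red cell line rose in the toxin-treated lungs, while most markers of the fixed erythroid list did not pass. Klf1, the master transcription factor of red cell precursors (ENSMUSG00000054191, chromosome 8, 84901928 to 84905295), rose from 1.44 ± 1.4 to 16.0 ± 2.67 RPM (log2 fold change 2.93 ± 0.34, adjusted p = 0.0145). Epb42, which encodes a protein of the red cell membrane skeleton (ENSMUSG00000023216, chromosome 2, 121017891 to 121037072), rose from 2.45 ± 0.821 to 23.1 ± 5.22 RPM (2.81 ± 0.21, adjusted p = 0.0058). The blood group genes Kel (2.53 ± 0.30) and Ermap (2.38 ± 0.22) and the anion exchanger Slc4a1 (2.02 ± 0.23, from 19 ± 7.49 to 76.8 ± 10.3 RPM) rose as well. Over all 16708 genes tested, 46 were higher and 1 was lower in DT (limma, Benjamini-Hochberg below 0.05), and 40 of the 47 changed more than 2-fold on the log2(RPM + 1) scale. Without PBS mouse 1, 56 were higher and 10 lower, and 41 of the 46 were shared. Without DT mouse 1, limma called 0 higher and 0 lower (630 and 497 at an unadjusted p under 0.05, against 836 and 673 with all 6 mice, where chance gives 835 over both directions together). Without DT mouse 3, 14 were higher and 0 lower (619 and 470 unadjusted), without DT mouse 2, 51 and 90, and without PBS mouse 3, 41 and 0. Fold changes moved less than the calls: that of Epb42 was 2.65 without DT mouse 1, with an adjusted p of 0.0673.

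Others among the 12 largest rises were Btnl10 (2.92 ± 0.34), Nog, which encodes the BMP antagonist noggin (2.44 ± 0.22, from 2.72 ± 1.07 to 18.6 ± 1.71 RPM), Cldn13 (2.20 ± 0.26), Hemgn (2.17 ± 0.31), Gm11274 (2.15 ± 0.17), Trim10 (2.12 ± 0.22) and Tspo2 (2.09 ± 0.17). The groups did not overlap in 14.4% of all tested genes, counting both directions, against 10% by chance. The only gene that fell was Ces2e, a carboxylesterase (ENSMUSG00000031886, chromosome 8, 104926260 to 104934672), which dropped by 0.49 on the log2 scale (26.5 ± 0.89 to 18.6 ± 0.678 RPM, adjusted p = 0.039). The Ces2e call was lost without any 1 of the 6 mice, with an adjusted p between 0.0519 (without PBS mouse 1) and 0.169 (without PBS mouse 2). Without DT mouse 1 the adjusted p of Nog was 0.0876 and that of Hemgn 0.234.

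Of the 12 erythroid markers, 3 rose over all genes and 3 when adjusted over the list alone, Epb42 and Slc4a1 among them. The list lay higher as a whole (median 0.23, camera adjusted p = 5.06e-06; adjusted p = 0.378 with an estimated correlation). Without PBS mouse 1 the list again had 3 members higher (camera adjusted p = 0.000104). Without DT mouse 1 the calls for Epb42 (0.0673) and Slc4a1 (0.15) were lost, and without DT mouse 3 that for Slc4a1 (0.0637). The haem synthesis gene Alas2 (0.89 ± 0.35, but 0.44 without PBS mouse 1) did not pass. The globin genes Hba-a1 (0.18 ± 0.12) and Hbb-bs (-0.15 ± 0.12) stood at only 14.6 ± 1.45 and 10.6 ± 0.868 RPM in PBS; these 3 were named after their values were seen.

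**Figure D2:**
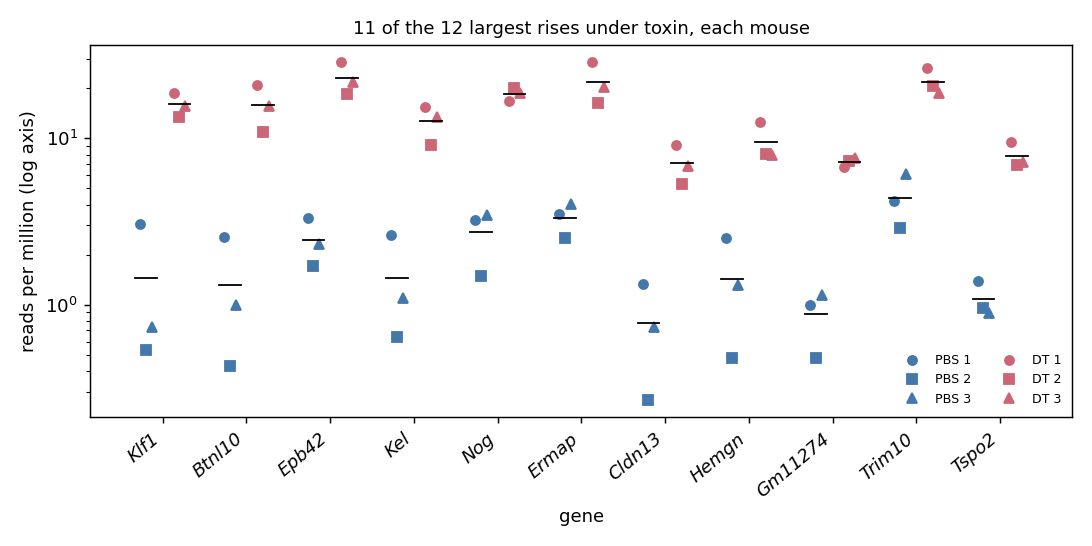
Level (RPM, log axis) of 11 of the 12 genes with the largest rises in each mouse, with horizontal lines for group means (n = 3 mice per group). No overlap between the groups was a condition for being shown, and PBS mouse 1 lies with the PBS group, for example at 3.33 RPM for Epb42 against 18.5 to 28.8 in DT.

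Reads of histone genes were higher as a family, at low levels. Of 45 tested, 4 rose over all genes and 24 when adjusted over the list alone, the median log2 fold change was 0.55, and 41 of the 45 were positive (camera adjusted p = 2.17e-25; adjusted p = 0.102 with an estimated correlation). The 4 were Hist1h3i (1.75 ± 0.17, from 0.124 ± 0.132 to 2.78 ± 0.556 RPM), Hist1h2bn (1.63 ± 0.17), Hist1h2ac (1.60 ± 0.22) and Hist1h3d (1.16 ± 0.16), all on chromosome 13. The 4 calls were lost without DT mouse 1, with adjusted p from 0.0849 for Hist1h3i to 0.223 for Hist1h3d, and 5 members passed without PBS mouse 1. Histone copies are near-identical and lie close together, Gm11274 (start 21769125) among them, and with the use of strand not given their reads can be shared. The mean log2(RPM + 1) of the family was only 1.47 in PBS and 2.03 in DT. The kit selects polyadenylated RNA, and how far histone transcripts carry such a tail was not tested. The rise in reads is therefore no measure of total histone transcripts. Cell cycle genes (28 tested, 0 past the test over all genes and 0 adjusted over the list alone) lay slightly higher, with a median of 0.10 and Mki67 at 0.32 ± 0.14 and Top2a at 0.19 ± 0.15, or 0.15 and 0.01 without PBS mouse 2 (camera adjusted p = 0.0449; adjusted p = 0.878 with an estimated correlation). That list's call ended without PBS mouse 2, where its direction turned (adjusted p = 0.445), and without DT mouse 1 (0.891), and it missed the threshold on the deposited values (0.0532). Its scores per mouse gave an exact permutation p of 0.7.

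Classical monocyte and neutrophil genes were higher as lists, with 0 members of these lists past the test over all genes (limma). The lists share Mmp8 (0.61 ± 0.1), named after its values were seen, so they are not fully separate results. All 10 classical monocyte markers were positive (median 0.39, 6 higher when adjusted over the list alone, camera adjusted p = 5.21e-07; adjusted p = 0.378 with an estimated correlation), among them the chemokine receptor Ccr2 (0.33 ± 0.11, 58.2 ± 9.17 and 72.8 ± 5.59 RPM, but 0.21 without PBS mouse 1) and the proteoglycan Vcan (0.72 ± 0.21). The 13 neutrophil markers lay between 0.00 and 1.17 (median 0.23, 3 higher when adjusted over the list alone, camera adjusted p = 0.000169; adjusted p = 0.378 with an estimated correlation), including Ltf (0.25 ± 0.17) and Csf3r (0.06 ± 0.09). With each mouse left out, Ltf ran from 0.11 (DT mouse 2) to 0.41 (PBS mouse 2) and Csf3r from -0.02 (PBS mouse 1) to 0.13 (PBS mouse 3).

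Lists of NF-kappaB targets and type I interferon genes were slightly higher, with 0 members past the test over all genes (limma). PBS mouse 1 lay within the DT range in both. Its mean score was 5.03 for NF-kappaB targets (DT 4.99 to 5.10) and 5.37 for type I interferon genes (DT 5.29 to 5.39). Scores per mouse gave an exact permutation p of 0.2 and 0.3. NF-kappaB targets (19 tested, 3 higher when adjusted over the list alone) had a median of 0.19 and camera adjusted p = 8.96e-05, or adjusted p = 0.735 with an estimated correlation, with Icam1 at 0.08 ± 0.05 and Sod2 at 0.02 ± 0.05. Type I interferon genes (25 tested, 2 higher when adjusted over the list alone) had a median of 0.08 (camera adjusted p = 0.00482; adjusted p = 0.878 with an estimated correlation), with Ifit2 at 0.13 ± 0.04 and Stat2 at -0.03 ± 0.07. The interferon call ended without PBS mouse 2 (0.0735), PBS mouse 3 (0.131) or DT mouse 3 (0.0884). The interferon-gamma response list pointed down, with 17 of 21 members negative, a median of -0.06 and 0 adjusted over the list alone, and did not pass (camera adjusted p = 0.055; adjusted p = 0.878 with an estimated correlation). It did under median-of-ratios scaling (0.034), the trimmed mean of M-values (0.0335), camera on ranks (0.0279) and no filter on low values (0.042). It also did without PBS mouse 2 (0.0323), PBS mouse 3 (0.0162) or DT mouse 3 (0.00868).

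B cell and natural killer cell markers were lower as lists, with 0 members past the test over all genes (limma). B cell markers (12 tested, 1 lower when adjusted over the list alone) had a median of -0.30 (camera adjusted p = 0.00378; adjusted p = 0.878 with an estimated correlation), with Cd22 at -0.10 ± 0.19 (-0.31 without PBS mouse 1 to 0.08 without PBS mouse 3). All 12 markers of natural killer and cytotoxic cells were negative (median -0.21, 0 adjusted over the list alone, camera adjusted p = 0.00275; adjusted p = 0.878 with an estimated correlation), with perforin, Prf1, at -0.50 ± 0.25 and Gzma at -0.15 ± 0.15. These ran from -0.77 and -0.28 without PBS mouse 1 to -0.30 and -0.06 without PBS mouse 3. T cell markers did not pass as a list (12 tested, 0 past the test over all genes and 0 adjusted over the list alone, camera adjusted p = 0.318), and lay lower only without PBS mouse 1 (0.00312). Cd3e (log2 fold change -0.17 ± 0.13, but -0.07 without PBS mouse 3) stood at 13.9 ± 1.94 RPM in PBS and 12.3 ± 1.21 in DT. PBS mouse 1 lay 0.76 below the mean of the other PBS mice in the B cell list and 0.55 below in the cytotoxic list, on the log2 scale. Scores per mouse gave an exact permutation p of 0.4 for the B cell list and 0.3 for the cytotoxic list. The B cell call ended without PBS mouse 2 (0.0856), PBS mouse 3 (0.213) or DT mouse 3 (0.0604), and the natural killer call without PBS mouse 2 (0.101), PBS mouse 3 (0.131) or DT mouse 1 (0.0935).

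Genes tied to pulmonary hypertension did not pass as a list (32 tested, 0 past the test over all genes and 0 adjusted over the list alone, median 0.03, camera adjusted p = 0.467). Bmpr2, the receptor most often mutated in heritable disease, was at 115 ± 3.85 RPM in PBS and 122 ± 3.88 in DT, and the vasoconstrictor gene Edn1 at 68.4 ± 5.91 and 67.7 ± 2.22. Epas1 and the phosphodiesterase gene Pde5a differed by 0.04 ± 0.06 and -0.05 ± 0.04 on the log2 scale. Targets of the hypoxia-inducible factors did not pass as a list either, in mice that were all hypoxic (30 tested, 0 past the test over all genes and 0 adjusted over the list alone, median 0.03, camera adjusted p = 0.767), with Vegfa at 0.03 ± 0.06 and Vldlr at -0.06 ± 0.05.

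Lists for smooth muscle, fibroblasts and endothelium did not pass. Smooth muscle contractile genes (14 tested, camera adjusted p = 0.861), fibroblast markers (15 tested, 0.465) and pan-endothelial markers (12 tested, 0.767) each had 0 members past the test over all genes and 0 adjusted over the list alone. Their members included Acta2 (0.07 ± 0.06) and Mylk (0.07 ± 0.05), Col1a1 (0.02 ± 0.07) and Pdgfra (0.06 ± 0.04), and Pecam1 (0.16 ± 0.09, but 0.07 without DT mouse 1), Cdh5 (0.03 ± 0.05) and Kdr (0.10 ± 0.05). The smooth muscle list had a median of 0.02 and a mean of -0.01.

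Matrix genes were marginally higher as a list (28 tested, 0 past the test over all genes and 0 adjusted over the list alone, median 0.06, camera adjusted p = 0.0319; adjusted p = 0.878 with an estimated correlation), with Thbs1 at 0.29 ± 0.09 (0.19 without PBS mouse 2) and Col4a2 at 0.06 ± 0.05 (0.01 without DT mouse 1). That call ended without PBS mouse 2 (0.129), PBS mouse 3 (0.131) or DT mouse 1 (0.201). Chemokines and cytokines did not pass (37 tested, 0 over all genes and 0 adjusted over the list alone, camera adjusted p = 0.465). Among them, Il6 was at 1.09 ± 0.624 RPM in PBS and 2.75 ± 0.204 in DT (0.89 ± 0.22, adjusted p = 0.283), Ccl2 differed by 0.76 ± 0.38, Csf1 by 0.12 ± 0.05 and Cxcl12 by 0.00 ± 0.07 (-0.01 under upper-quartile scaling). Ccl2 passed without PBS mouse 1 (1.27, adjusted p = 0.0193) and stood at 0.44 without PBS mouse 2. Ccl22 of the same list, named after its values were seen, pointed down. It was at 28.8 ± 11 RPM in PBS and 10.7 ± 7.25 in DT (-1.46 ± 0.45, limma adjusted p = 0.411). Alveolar type 2 markers did not pass (13 tested, 0 over all genes and 0 adjusted over the list alone, camera adjusted p = 0.148), with Abca3 at 195 ± 11.4 and 211 ± 12 RPM, but did without DT mouse 2 (0.0415). The surfactant gene Sftpc stood at only 9.04 ± 0.12 RPM in PBS and 8.78 ± 0.602 in DT, although it is a main product of these cells. In these values only 3 of 24777 genes of 300 or more exonic bases exceeded 1 read per exonic base. Whether values follow abundance in genes dense in reads was not tested. Small differences in abundant genes of the class II, smooth muscle, fibroblast, endothelial and alveolar type 2 lists are therefore no evidence of no change. The same holds for abundant genes of the pulmonary hypertension list and among targets of the hypoxia-inducible factors.

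Heart and fat genes varied between libraries. Cardiac muscle markers (12 tested, 0 past the test over all genes and 0 adjusted over the list alone, median -0.40) lay lower in DT as a list (camera adjusted p = 0.000509; adjusted p = 0.802 with an estimated correlation), and so did adipose markers (9 tested, 0 and 0, median -0.51, camera adjusted p = 0.0173; adjusted p = 0.878 with an estimated correlation). The sarcomere gene Ttn stood at 61.6 and 66.2 RPM in DT mice 1 and 3 but at 323 in DT mouse 2 and 177 to 259 in PBS. Myh6 had a log2 fold change of -0.24 ± 0.09, and the fat genes Plin4 and Car3 of -0.38 ± 0.39 and -0.61 ± 0.46, which ran from -0.85 and -1.15 without DT mouse 2 to -0.02 and -0.23 without DT mouse 1. The adipose call ended without PBS mouse 2 (0.359), PBS mouse 3 (0.0664), DT mouse 1 (0.319) or DT mouse 3 (0.152). Without DT mouse 2, the heart genes Ttn (-1.65, adjusted p = 0.00573) and Myh6 (-0.35, 0.0257) passed and 90 genes in all were lower in place of 1.

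**Figure D3:**
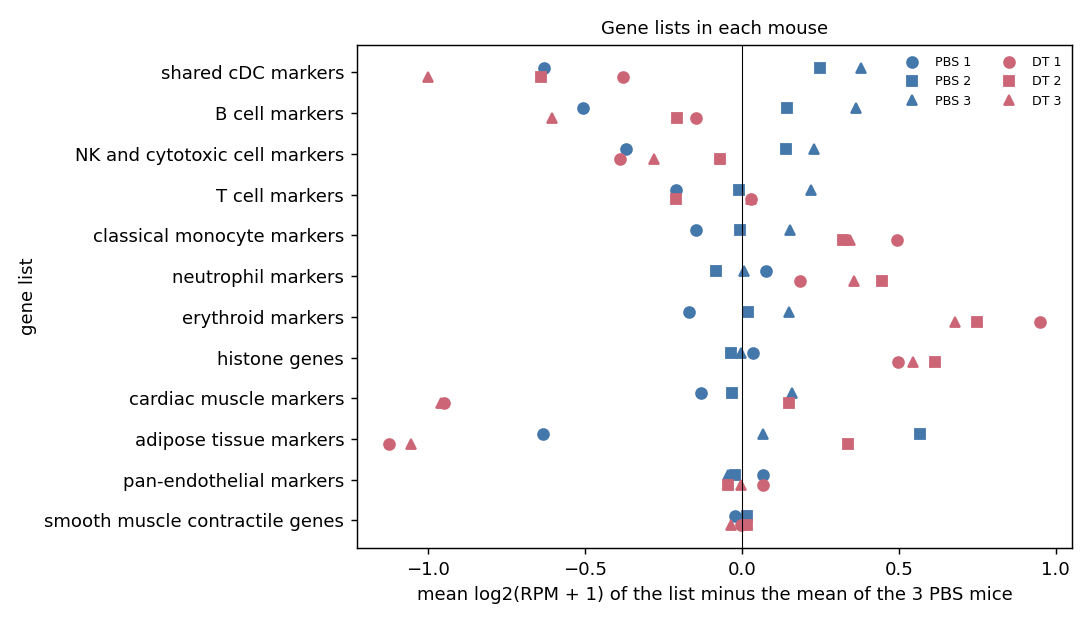
Mean log2(RPM + 1) of 12 gene lists in each mouse, shown as the difference from the mean of the 3 PBS mice. PBS mouse 1 lies with the toxin group in dendritic markers (a score of 3.91 against 4.79 and 4.92 in the other PBS mice), and DT mouse 2 lies with the PBS group in cardiac markers (5.13 against 4.03 and 4.02 in the other DT mice).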

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

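The trimmed mean of M-values, the other pseudocount, the deposited values without a pseudocount, the variance prior and the block with median-of-ratios scaling were chosen after the data were seen. The count of 46 genes higher in DT was within 1.5 times that number under the changes of scaling, filter, pseudocount and variance prior, under limma-voom (35) and against a minimum fold change of 1.2 (31), but the genes differed: 36 of the 46 were shared with the 38 called under median-of-ratios scaling, and 33 with the 40 called without a trend in the variance prior. Of the 19 named genes past the threshold, 9 lost their call without that trend, 6 under limma-voom, 6 on the deposited values, 4 under median-of-ratios scaling, 4 under the trimmed mean of M-values, 3 under upper-quartile scaling, 3 without a filter and 13 with a replicate block. The scalings moved the median of all genes by at most 0.01. The single gene lower became 0 under median-of-ratios scaling, the trimmed mean of M-values and the minimum fold change (79 lower at an unadjusted p under 0.05), and 2 under upper-quartile scaling. Nothing in the labels says that mouse numbers pair the groups, and within each group they follow the order of the numbers in the deposited column names. The values could not settle it, since only 3 same-numbered pairs exist. The correlations of same-numbered deviations were 0.084, 0.268 and -0.10. PBS mouse 2 correlated best with its own number, the highest correlation of any pair, while PBS mice 1 and 3 did not. With a replicate block, 8 genes were higher and 0 lower (855 and 783 at an unadjusted p under 0.05), and 1 and 0 with median-of-ratios scaling added. Leaving out each mouse gave 0 to 56 genes higher, the lowest without DT mouse 1, and 0 to 90 lower, the highest without DT mouse 2. The log2 fold changes of the 19 named genes past the threshold stayed at 0.85 to 1.15 times their value without each mouse; all 19 lost their call without DT mouse 1 and 12 without DT mouse 3; the cause was not tested. Those 19 were selected by passing: of the 76 other named genes, 49 moved by over 1.5 times without at least 1 mouse, many of them close to 0, and 17 changed sign in some setting. Of the 21 lists past the threshold, 9 stayed past it without each mouse in turn and 0 with an estimated correlation (shared cDC 0.735, cDC1 0.878, erythroid 0.378). Without each mouse the adjusted p was 1.73e-09 to 0.0344 for the shared cDC list, 9.47e-07 to 0.000137 for the erythroid list, 0.203 to 0.935 for the cDC2 list and 0.000464 to 0.257 for the cDC1 list. The cDC1 list also missed the threshold under median-of-ratios scaling (0.055), the trimmed mean of M-values (0.0556), the deposited values (0.0532) and the replicate block (0.119, or 0.121 with median-of-ratios scaling); the cause was not tested. Of the 21 lists, 2 missed it under median-of-ratios scaling, 2 under the trimmed mean of M-values, 4 on the deposited values, 3 with a replicate block, 1 with the other pseudocount and 1 with camera on ranks, among them the plasma cell, platelet, alveolar type 1 and cell cycle lists. The cell cycle list turned down without PBS mouse 2 (0.445) and ran from 0.000414 to 0.891 over the mice left out. Library size as the only scaling is what the deposited values already hold, and the planned negative binomial fits were not run because the deposited unit is log2.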

Other observations

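The tests of heart and fat tissue, of blood, of PBS mouse 1 (label, leukocytes and Y-linked genes) and of dense genes on their own scale were chosen only after the results were seen. Genes of the circadian clock moved in both directions: of 16 tested, 1 rose over all genes, and 3 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.785, median 0.00). The gene that rose was Nfil3, a repressor in the clock's output (21 ± 2.8 to 35.7 ± 1.89 RPM, log2 fold change 0.75 ± 0.10, limma adjusted p = 0.0279). The Nfil3 call was lost without PBS mouse 3 (0.0528), DT mouse 1 (0.194) or DT mouse 3 (0.141). Further clock genes, named after their values were seen, were Arntl (1.07 ± 0.31), Npas2 (1.05 ± 0.39), Clock (0.23 ± 0.06), Dbp (-0.37 ± 0.11) and Hlf (-0.34 ± 0.08), none of which passed over all genes. Glucocorticoid-induced genes (14 tested, 0 over all genes, 1 higher when adjusted over the list alone, median 0.09) and immediate early genes (18 tested, 0 over all genes, 2 higher when adjusted over the list alone, median 0.08) were higher as lists, with camera adjusted p = 0.00139 and 0.0018 and adjusted p = 0.378 and 0.735 with an estimated correlation. Their most abundant members were Klf9 (0.02 ± 0.04) and Per1 (0.04 ± 0.04), and Egr1 (0.16 ± 0.06) and Jun (0.06 ± 0.07).

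Plasma cell markers (8 tested, 2 lower when adjusted over the list alone, median -0.27, camera adjusted p = 0.0492), skeletal muscle markers (9 tested, -0.27, 0.00774), eosinophil, basophil and mast cell markers (7 tested, 0.47, 0.0132) and alveolar type 1 markers (12 tested, 0.06, 0.0492) also passed as lists, with 0 members past the test over all genes. Their adjusted p = 0.735, 0.378, 0.378 and 0.878 with an estimated correlation. The plasma cell call ended without PBS mouse 2 (0.14), PBS mouse 3 (0.285), DT mouse 2 (0.129) or DT mouse 3 (0.0884), and was lost under median-of-ratios scaling (0.096), the trimmed mean of M-values (0.0982), the other pseudocount (0.0556), the deposited values (0.0565), a replicate block (0.0986) and camera on ranks (0.144). The call ended for the skeletal muscle list without PBS mouse 3 (0.0619). Like the cardiac score, the skeletal muscle score was higher in DT mouse 2 (1.82) than in DT mice 1 and 3 (1.51 and 1.57), with 1.87 to 1.97 in PBS. The mast cell call ended without DT mouse 2 (0.0552), and the alveolar type 1 call without PBS mouse 1 (0.0909), PBS mouse 3 (0.294) or DT mouse 1 (0.481) and on the deposited values (0.0507).

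Platelet markers (11 tested, 0 over all genes and 0 adjusted over the list alone, median 0.27) were higher as a list (camera adjusted p = 0.0238; adjusted p = 0.878 with an estimated correlation), with the integrin Itga2b at 0.47 ± 0.21 (0.71 without DT mouse 1); the call ended without PBS mouse 2 (0.0735), PBS mouse 3 (0.131), DT mouse 2 (0.129) or DT mouse 3 (0.394), or with a replicate block (0.0624). Transcripts of both sex chromosome types were present in every lung: Xist, made from the inactive X chromosome, stood at 402 ± 40.3 RPM in PBS and 438 ± 11.6 in DT, and the Y-linked Ddx3y at 7.73 ± 4.19 and 9.38 ± 1.54, with 3.55 RPM in PBS mouse 1.

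Of the 46 genes higher in DT, 18 were picked after their values were seen as known from red cells or their precursors, with no enrichment test behind that number; this set replaced the 3 members of the fixed list used in a first run of the test. Heart or fat tissue taken along with some lungs could not be judged as the whole cause of their rise. With the fat score of each mouse in the model the median log2 fold change of these 18 genes was 1.87 (standard error 0.19). With the heart score it was 1.94 (0.25), against 2.05 without either. But the 18 were picked from called genes, which were high in DT mouse 2 as well. That mouse had a heart score of 5.13 (PBS 4.85 to 5.14) and a fat score of 3.88 (PBS 2.91 to 4.11), so the median could hardly fall. With the fat score 12 of the 18 passed. With the heart score 0 did, at a wider error, and 0 genes were called higher over all genes (limma). In that fit 18 had an unadjusted p under 0.05. Both fits had 1 residual degree of freedom less. More cells of the erythroid line may lie in the toxin-treated lungs, as a hypothesis: in an added list of erythroid genes written before its values were seen, 14 of 19 were positive (camera p = 4.96e-06; p = 0.0484 with an estimated correlation), but the median of 0.17 was below the 0.5 set beforehand, 0 passed over all genes and 9 when adjusted over the list alone. More blood left in the lungs stays open: the 4 globin genes differed by only -0.15 to 0.28, which would argue against it, but whether values follow abundance at their median of 0.32 reads per exonic base was not tested.

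PBS mouse 1 had low dendritic and lymphocyte genes, and its NF-kappaB and type I interferon scores lay with the DT mice. The number in its deposited column name is the lowest and stands apart from those of the other mice. Whether it was handled apart from them was not tested. A wrong group label was argued against: over the 56 genes higher in DT without that mouse, it lay at a median of 0.18 of the way from the other PBS mice to the DT mean (quartiles 0.03 and 0.37), although 9 of the 10 lower genes were nearer the DT mean. This bound replaced a stricter first version, at most 0.1 of the 56 genes nearer the DT mean, which 8 of the 56 missed. An equally lower share of all leukocytes was argued against by neutrophil markers alone. These lay 0.12 ± 0.09 above the other PBS mice, while its B cell markers had a gap of -0.76 ± 0.12 (SE over genes). That error is taken over related genes in 1 mouse and does not measure the spread between mice. The pattern expected of such a share also named monocytes and macrophages. A lower share of several types stays open, with gaps of -0.22 ± 0.11 for classical and -0.23 ± 0.09 for nonclassical monocytes, -0.16 ± 0.10 for interstitial and 0.02 ± 0.07 for alveolar macrophages, -0.32 ± 0.13 for plasmacytoid dendritic cells and -0.32 ± 0.09 for T cells. Fewer cells with a Y chromosome in this mouse is a possibility only: all 4 Y-linked genes had their lowest value in it. That could mean a lower share of transplanted cells if the donors were male, a point the labels do not give. The 4 genes are read from the same cells and are not separate evidence. Whether fewer such cells would lower dendritic and lymphocyte genes was not tested.

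Abundant genes rarely exceeded 1 read per exonic base (99th percentile 0.541), and the 100 genes with most reads had a median exonic length of 13044 bases against 3542 for all genes with a read. Removal of reads that repeat a position before counting might produce such a ceiling, though no source used here names that step. It would press the spread of dense genes below counting noise, and the test set beforehand did not show this: among 390 genes over 0.5 reads per exonic base the median variance over mean of the PBS libraries was 1.94. Taken alone, that value argues against it, but the bound of 1 left out offsets of these genes as a set, 3.5% in PBS and 5.3% in DT, whose variance grows with the square of the read number. On the genes' own scale, a check added after that value was seen, the ratio was 0.729 in PBS and 0.509 in DT, against 0.693 from counting noise alone, so the question stays open and no biological explanation was tested.

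Among the 10 splits of the 6 mice into groups of 3, the real split gave 46 genes higher and 1 lower and the highest of the others gave 0 for both, so 1 split gave as many; 10 splits are too few for a share under 0.05.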
